A study of Mus musculus with 13 samples.

How the data were processed

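MicroRNA levels were measured on 13 primary abdominal neuroblastomas of TH-MYCN mice, a strain in which MYCN is expressed in the sympathetic lineage and tumours arise spontaneously. The labels assigned 6 tumours to wild-type caspase-8 without bone marrow metastasis and 7 to caspase-8 deficiency with bone marrow metastasis, and called them biological replicates. Genotype and metastasis changed together, so that the comparison is between tumours that differ in both. Per the labels' protocols, total RNA was extracted with Trizol and labelled with Cy3. Each sample was hybridised to 1 Agilent mouse miRNA array of 1 colour.

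The deposited scanner files held the intensity of each spot on a linear scale, background-subtracted and detrended per the file headers, with no scaling between arrays. They named Feature Extraction version 10.7.3.1, whereas the submitters' processing notes named version 10.5.1.1. Detection and outlier marks of the scanner software, which are deposited yes or no values and no measurement of level, were used as other information per the file headers. The deposited series matrix held log2 values that the authors had made equal in distribution across arrays: its sorted columns differed by at most 0.00219, and every column had a median of 3.82. All 13 of its columns matched their own array best after centring. Its background step, probe summary and software are not given in the sources used here, and it served as an alternative.

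Each array carried 47604 spots, of which 2164 were controls and were left out. The 1079 mouse miRNAs were each read by 1 to 4 probes, with 10 to 40 spots per probe. Spots of a probe without outlier marks were averaged and probes of a miRNA were summed. Sums were divided by the array's 75th percentile over the 294 mouse miRNAs detected on all 13 arrays, multiplied by the geometric mean of these percentiles, raised to a floor of 17.2 (percentile 1 of detected values, 4.1 on the log2 scale) and converted to log2. The 419 mouse miRNAs detected on at least 6 arrays were tested. No spot was saturated. Because probes differ in brightness, levels of different miRNAs were ranked against each other only to choose which to name. The number of arrays limits the precision: the median half-width of the 95% interval of a difference was 0.626 on the log2 scale.

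Differences are given as deficient minus wild type on the log2 scale. They were tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3, files read with version 1.17.8 of the data.table package), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Of 20 miRNA lists written from background knowledge, 15 had at least 3 tested members and were tested with limma's camera at its preset correlation of 0.01, adjusted over the 15 lists. The mean of a list per tumour, the number of detected miRNAs, the 75th percentile and the summed signal were compared by two-sided exact permutation over all 1716 splits into 6 and 7. Where 1 tumour was left out, all splits of the remaining tumours were used. The arrays lay on 2 slides, which each held both groups but unequally. Slide 1 held 2 wild-type and 5 deficient tumours, and slide 2 held 4 wild-type and 2 deficient tumours. Group and slide are thus partly confounded, and each difference within a slide rests on only 2 tumours in 1 of the groups. Results are given with slide as a block and within slides. Exact permutation with slide as a block ran over the 315 splits that kept the group sizes of each slide. Correlations across tumours used 100000 permutations.

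Named miRNAs followed a rule: those past the threshold with the largest differences, the smallest p values where fewer than 10 passed, the 2 tested members of each described list with the highest mean level, and all tested forms of miR-7a, 7b, 29b, 34a, 17, 124, 10b, 21, 126, 142 and 145 and of miR-451. Forms of these on the array that were not tested were miR-10b-3p, detected on 4 arrays, and miR-124-5p, miR-145-3p, miR-29b-1-5p, miR-29b-2-5p and miR-34a-3p, detected on none. Groups, lists, tests, this rule and most alternatives were fixed before the data were examined. The alternatives covered scaling, background, probe summary, detection filter, floor, variance model, array weights, slide, replicate number, the series matrix, other list tests and leaving out each tumour. Normexp with an offset of 50 was run on median spot and background signals, since the mean signal column it was planned for was not found in the files. That choice, the omission of 3 tumours with high muscle miRNAs, and the omission of 33 miRNAs that followed a viral probe with a correlation of at least 0.9 were chosen after seeing the data. The reference gene table was of the GRCm38.p6 assembly while the array design named mm9, so that it was used only for which genes neighbour each other and no coordinates are given.

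The test was checked on simulated data for this comparison, with 419 miRNAs and 20 simulations. Normal noise was drawn independently for each miRNA, and 20 miRNAs were changed by each size. It recovered 10.2% of miRNAs changed by 0.5, 52.2% of those changed by 1 and 87.2% of those changed by 2 on the log2 scale. False calls made up 5.1% of all calls. Many measured miRNAs vary together, so that these rates need not hold for the real arrays.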

Results

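The comparison asks which miRNAs differ between primary neuroblastomas of TH-MYCN mice with wild-type caspase-8 and no bone marrow metastasis (n = 6) and caspase-8-deficient tumours with bone marrow metastasis (n = 7). Caspase-8 is the initiator protease of death receptor apoptosis. The arrays detected 338 to 469 mouse miRNAs per tumour, and 547 of the 1079 mouse miRNAs were detected in none. Wild-type tumours had 409.2 ± 43.3 detected miRNAs (SD, n = 6) and deficient tumours 416 ± 31.4 (SD, n = 7), a difference of 6.83 (exact permutation p = 0.751, adjusted p = 0.751 over 3 values), and of 26.05 with slide as a block (exact permutation p = 0.165). The difference was −7.4 without wild-type replicate 2 and −2 without deficient replicate 4. The summed miRNA signal was 691000 ± 199000 (SD, n = 6) in wild-type and 827300 ± 84800 (SD, n = 7) in deficient tumours (exact permutation p = 0.137, adjusted p = 0.411). With slide as a block its difference was 210300 (exact permutation p = 0.0159, adjusted p = 0.0477). The 75th percentile of the array differed by 170.4 (exact permutation p = 0.36, adjusted p = 0.54), and by 329.9 with slide as a block (exact permutation p = 0.0667, adjusted p = 0.1).

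No miRNA passed the threshold. Of the 419 miRNAs tested with limma, 0 were higher and 0 were lower at an adjusted p under 0.05, and the smallest adjusted p was 0.448. At an unadjusted p under 0.05 there were 16, 10 higher and 6 lower in deficient tumours, where chance alone gives about 21. With slide as a block the count was also 0, with 12 at an unadjusted p under 0.05.

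The 10 miRNAs with the smallest p are named as not past the threshold. Of these, 7 had higher means in deficient tumours. miR-712-3p was at 5.18 ± 0.63 (SD, n = 6) in wild-type and 6.41 ± 0.49 (SD, n = 7) in deficient tumours, a difference of 1.23 (SE 0.30, limma adjusted p = 0.448), with 1.13 when slide was a block, 1.20 within slide 1 and 1.05 within slide 2. The differences were 1.08 (SE 0.35) for miR-1907, 1.20 (SE 0.45) for miR-546, 0.99 (SE 0.42) for miR-3113-5p and 0.76 (SE 0.32) for miR-5109. For miR-145-5p, which is abundant in smooth muscle, the difference was 0.70 (SE 0.28), and for miR-301b-3p it was 0.68 (SE 0.27). The other 3 had lower means. The difference was −0.74 (SE 0.24) for miR-598-3p, −1.15 (SE 0.41) for miR-153-3p, a miRNA of neurons, and −0.86 (SE 0.35) for miR-29b-3p, which targets collagen transcripts. Apart from miR-712-3p, these had a limma adjusted p of 0.589. Several lay close to background. miR-1907 and miR-546 were detected in 3 of 6 wild-type and 6 of 7 deficient tumours. miR-712-3p and miR-145-5p were detected in 4 wild-type and 7 deficient tumours, and miR-3113-5p in 5 and 7. miR-1907 was at the floor in wild-type replicates 2 and 3, and miR-153-3p in deficient replicates 3 and 7. Within both slides all 10 kept the direction of the pooled difference, which their choice by p in these same tumours favours. Their smallest within-slide differences were 0.0914 for miR-301b-3p and −0.167 for miR-29b-3p, both on slide 1. With normexp background the differences were −0.474 for miR-598-3p, 0.0849 for miR-712-3p, 0.0924 for miR-1907, 0.084 for miR-546, 0.0318 for miR-145-5p, 0.11 for miR-301b-3p, 0.301 for miR-3113-5p and −0.35 for miR-153-3p. With 4 times the floor they were 0.362 for miR-712-3p, 0.119 for miR-1907, 0.549 for miR-546, 0.00935 for miR-145-5p and −0.24 for miR-153-3p. With the mean of log2 probe levels they were 0.491 for miR-712-3p, 0.632 for miR-546, 0.325 for miR-301b-3p and −0.489 for miR-153-3p. The series matrix values gave 0.733 for miR-712-3p, 0.681 for miR-1907, 0.751 for miR-546, −0.672 for miR-153-3p and 0.134 for miR-5109, which was also 0.134 with quantile normalization. Array weights gave −0.573 for miR-29b-3p and 0.241 for miR-301b-3p, slide as a block 0.658 for miR-3113-5p, and the total gene signal 1.33 for miR-145-5p.

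**Figure D1:**
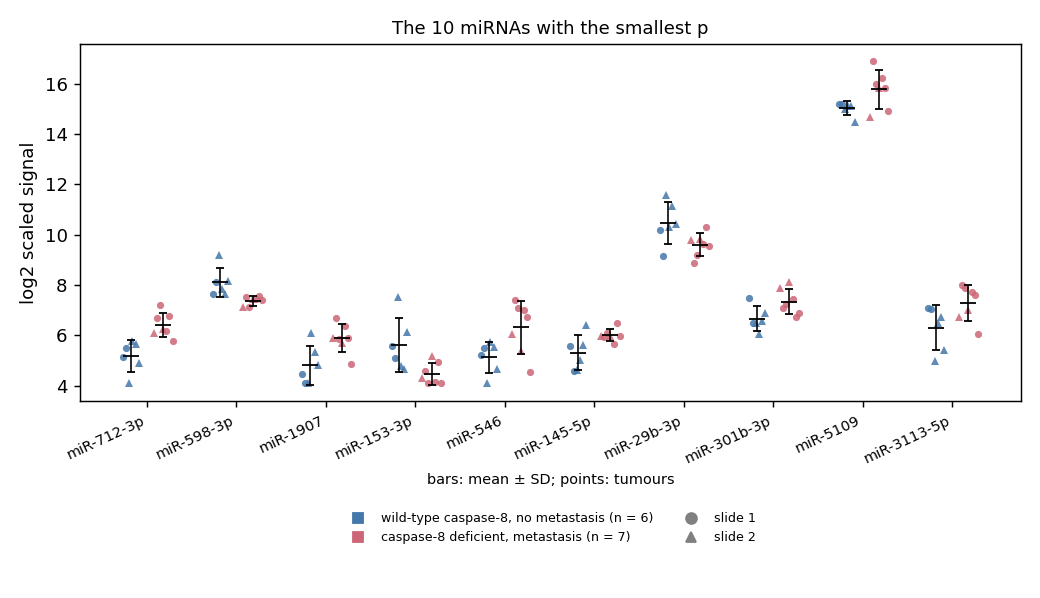
Levels of the 10 miRNAs with the smallest p (x axis) as log2 scaled signal (y axis), with 1 point per tumour, circles for slide 1, triangles for slide 2, and bars for mean ± SD of 6 wild-type and 7 deficient tumours. The groups overlap in most of them, and none passed the threshold (smallest adjusted p = 0.448).

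Groups of related miRNAs were compared through the lists. At camera's preset correlation 5 of 15 lists passed an adjusted p of 0.05, and with an estimated correlation 0 did, with adjusted p = 0.485 for each of the 5 except the miR-17-92 list, where adjusted p = 0.585. By fry 0 lists passed, with a smallest adjusted p of 0.433. In every list 0 members passed, over all tested miRNAs and adjusted over the list alone. The mean of a list per tumour separated the groups in no list by exact permutation (smallest adjusted p = 0.366). Of the 44 miRNAs named apart from the 10 above, 22 had differences of opposite sign within the 2 slides.

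The miR-17-92 cluster and its paralogs, targets of MYC proteins that promote proliferation, had higher means in deficient tumours for 14 of 15 tested members. The mean difference was 0.235 (camera adjusted p = 0.00625, and adjusted p = 0.585 with an estimated correlation). It was −0.0923 within slide 1, 0.463 within slide 2 and 0.176 with slide as a block. Without wild-type replicate 4 it was 0.165 (camera adjusted p = 0.0624), and with array weights 0.0818 (adjusted p = 0.426). miR-19b-3p differed by 0.26 (SE 0.19), miR-20a-5p by 0.24 (SE 0.21), miR-17-5p by 0.11 (SE 0.17) and miR-17-3p by 0.21 (SE 0.18). Without wild-type replicate 4 these 4 differed by 0.148, 0.116, 0.0286 and 0.0893, and within slide 1 by −0.189, −0.163, −0.115 and 0.00404. The mean difference of the list was 0.428 without scaling, 0.128 with normexp background and 0.114 with no filter on detection.

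All 3 tested members of the miR-29 family had lower means in deficient tumours, with a mean difference of −0.638 (camera adjusted p = 0.0131, and adjusted p = 0.485 with an estimated correlation). It was −0.089 within slide 1 and −0.662 within slide 2, and −0.366 with slide as a block (camera adjusted p = 0.0559). Without wild-type replicate 5 it was −0.533 (camera adjusted p = 0.0523). With no filter on detection it was −0.317. miR-29a-3p differed by −0.52 (SE 0.35), by −0.202 with slide as a block, 0.181 within slide 1 and −0.613 within slide 2, and by −0.788 without wild-type replicate 2.

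Of the 19 tested neuronal miRNAs 13 had lower and 6 higher means in deficient tumours, with a mean difference of −0.346 (camera adjusted p = 0.0321, and adjusted p = 0.485 with an estimated correlation). It was −0.449 within slide 1, −0.176 within slide 2 and −0.317 with slide as a block. The median difference was −0.249, and the members differed much in size. Outside the naming rule, the largest differences were −1.741, −1.128 and −0.788 for forms of miR-129, −0.919 for miR-132-3p and −0.848 for miR-138-5p, beside miR-153-3p. The 6 members with higher means reached 0.554 (miR-9-5p). miR-218-5p, abundant in motor neurons, differed by 0.06 (SE 0.26), miR-128-3p by −0.25 (SE 0.21) and miR-124-3p, the main miRNA of differentiated neurons, by −0.31 (SE 0.26). miR-218-5p was −0.438 within slide 1 and 0.497 within slide 2, and miR-128-3p was −0.152 without wild-type replicate 2 and −0.385 without wild-type replicate 4. The list gave −0.15 without scaling, −0.228 with normexp background and −0.184 with no filter on detection. The call was lost without wild-type replicate 1, 2 or 3 or deficient replicate 3, 5 or 7 (adjusted p of 0.0693, 0.126, 0.151, 0.0623, 0.0813 and 0.071). The mean difference was −0.201 without wild-type replicate 3, where miR-124-3p differed by −0.0917, and −0.347 to −0.296 without each of the others.

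The 3 tested erythroid miRNAs, which are made in red cell precursors, had higher means in deficient tumours, with a mean difference of 0.928 (camera adjusted p = 0.0321, and adjusted p = 0.485 with an estimated correlation). It was 0.861 within slide 1, 1.31 within slide 2 and 1.08 with slide as a block. miR-451 was at 13.94 ± 1.25 (SD, n = 6) in wild-type and 14.89 ± 0.67 (SD, n = 7) in deficient tumours, and miR-144-3p differed by 0.72 (SE 0.44). The call was lost without wild-type replicate 1, 2, 3, 4 or 5 or deficient replicate 1 or 7 (adjusted p of 0.0534, 0.126, 0.107, 0.0525, 0.103, 0.11 and 0.0664). The mean difference in these cases was 0.968, 0.845, 0.61, 0.958, 0.867, 0.693 and 0.999. Without wild-type replicate 3 miR-451 differed by 0.608 and miR-144-3p by 0.359. The list gave 0.511 with normexp background and 0.607 with 4 times the floor (camera adjusted p = 0.149).

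The list of miRNAs from the imprinted cluster in an intron of Sfmbt2 had a mean difference of −0.697 and a median of −1.09, with 17 of 24 tested members lower in deficient tumours (camera adjusted p = 0.000104, and adjusted p = 0.485 with an estimated correlation). It was −0.481 within slide 1, −0.666 within slide 2 and −0.57 with slide as a block. Leaving out 1 tumour at a time gave −0.896 to −0.452, the latter without wild-type replicate 4, and kept the camera call at the preset correlation. With an estimated correlation the adjusted p was then 0.436 to 0.695. The mean difference was −0.402 with normexp background and −0.299 with no filter on detection. Of the 21 miRNA names in it, arms joined, 15 have a gene inside Sfmbt2 in the reference table. miR-466i-5p differed by −0.84 (SE 0.47) and miR-669n by −1.08 (SE 0.58), and by −0.699 without deficient replicate 2. The 15 members named 5p all had lower means and the 4 named 3p all had higher ones. The probe for the viral mghv-miR-M1-2-5p differed by −1.19 (exact permutation p = 0.12), and 15 members of the list followed it with a correlation of at least 0.9.

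**Figure D2:**
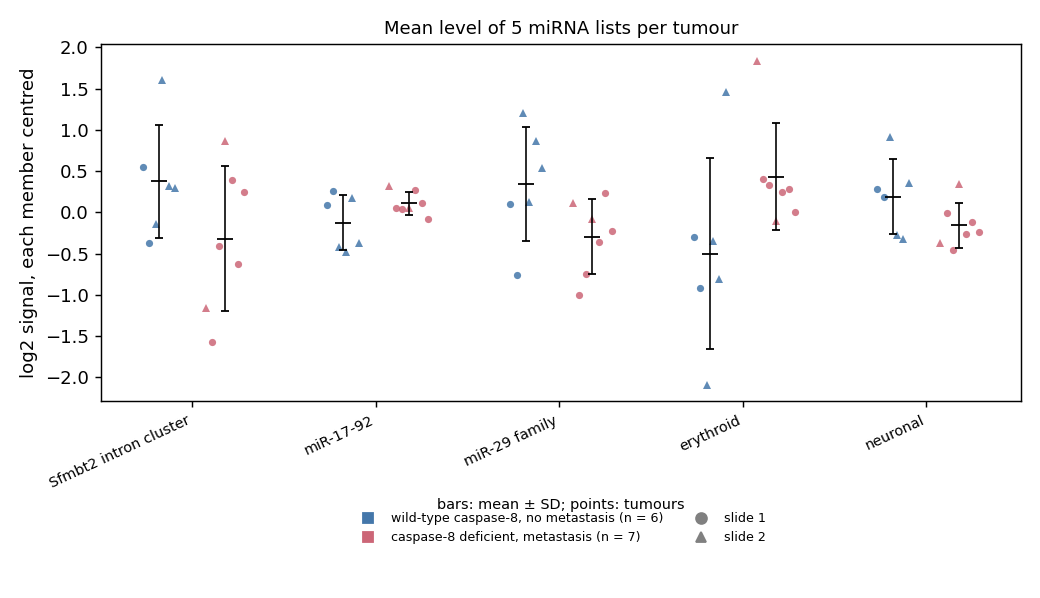
Mean level of 5 lists per tumour (x axis: list; y axis: log2 signal after centring each member), with 1 point per tumour, circles for slide 1, triangles for slide 2, and bars for mean ± SD of 6 wild-type and 7 deficient tumours. The groups overlap in each list, and deficient replicate 1 is the highest for the erythroid miRNAs at 1.84.

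The other 10 tested lists did not pass. All 3 tested members of the miR-34 family, targets of p53, had lower means (mean difference −0.36, adjusted p = 0.146, and −0.227 without wild-type replicate 3), with −0.12 (SE 0.38) for miR-34a-5p and −0.52 (SE 0.27) for miR-34b-5p. Without wild-type replicate 3 miR-34b-5p differed by −0.309, and miR-34a-5p was 0.376 within slide 1 and −0.485 within slide 2. The neuroendocrine and miR-183 cluster list had 6 tested members, miR-375-3p and forms of miR-7a and miR-7b. No miRNA of the miR-183 cluster was among them. Of the 6, 5 had lower means (mean difference −0.212, adjusted p = 0.171, and adjusted p = 0.585 with an estimated correlation). It was −0.137 without wild-type replicate 1 and −0.108 without deficient replicate 3. With slide as a block the mean difference was −0.309, with a camera adjusted p = 0.0336, an adjusted p = 0.468 with an estimated correlation and an exact permutation p = 0.111 for the mean per tumour. Among them miR-7a-5p differed by −0.50 (SE 0.25), miR-7b-5p by −0.29 (SE 0.26) and miR-375-3p by −0.14 (SE 0.33). The minor forms miR-7a-1-3p, miR-7a-2-3p and miR-7b-3p differed by −0.07, −0.29 and 0.01. With 1 tumour left out miR-7b-5p ranged from −0.456 (without wild-type replicate 5) to −0.138 (without wild-type replicate 6), and miR-7a-2-3p from −0.486 (without wild-type replicate 3) to −0.0789 (without wild-type replicate 2). The let-7 family, opposed by LIN28B in neuroblastoma, had a mean difference of 0.00877 over 13 members (adjusted p = 0.86), and it was −0.0124 after quantile normalization. let-7c-5p differed by −0.06 (SE 0.18) and let-7b-5p by −0.03 (SE 0.20), and both differences were positive without scaling. The 60 tested miRNAs of the imprinted Dlk1-Dio3 cluster, 54 of them detected on every array, differed by 0.0485 on average (adjusted p = 0.646), and by 0.00111 with slide as a block, with 0.88 (SE 0.56) for miR-494-3p and 0.13 (SE 0.20) for miR-154-3p. miR-494-3p was 0.509 without deficient replicate 2, 1.56 within slide 1 and 0.0756 within slide 2, and miR-154-3p was 0.0133 with slide as a block. The 16 tested members of the list on retinoic acid and neuronal differentiation gave 0.176 (adjusted p = 0.406, and 0.112 without wild-type replicate 6), with −0.12 (SE 0.17) for miR-125b-5p and −0.10 (SE 0.25) for miR-99a-5p. miR-125b-5p ranged from −0.196 (without wild-type replicate 4) to −0.0279 (without wild-type replicate 3). The list of the miR-290 and miR-302 clusters had 6 tested members, none of them a form of miR-302. It gave a mean of −0.0744 and a median of 0.0321 (adjusted p = 0.72), with 0.30 (SE 0.34) for miR-290-5p and −0.82 (SE 0.49) for miR-294-3p. The latter followed the probe for the viral mghv-miR-M1-2-5p with r = 0.98. miR-290-5p was 0.0576 without wild-type replicate 3, 0.14 without wild-type replicate 6 and 0.0426 with slide as a block, and miR-294-3p was −0.504 without deficient replicate 2.

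The list of miRNAs reported in tumour invasion and metastasis had 9 higher and 6 lower members of 15 tested (mean difference 0.156, adjusted p = 0.643). It was 0.0742 without wild-type replicate 3, 0.273 without wild-type replicate 5, 0.0927 without deficient replicate 1 and 0.259 without deficient replicate 2. miR-21-5p differed by −0.17 (SE 0.34), miR-21-3p by −0.29 (SE 0.36) and miR-30a-5p by 0.20 (SE 0.22). Without wild-type replicate 4 miR-21-3p was −0.0438 and miR-30a-5p 0.0432, without wild-type replicate 5 miR-21-3p was −0.0746, and without wild-type replicate 6 miR-30a-5p was 0.323. Within slide 1 miR-21-5p was 0.371 and miR-21-3p 0.356, and within slide 2 they were −0.409 and −0.527. miR-10b-5p varied more than most, at 8.27 ± 2.11 (SD, n = 6) in wild-type and 9.18 ± 1.93 (SD, n = 7) in deficient tumours, with a 95% interval of the difference from −1.25 to 3.06. Its difference was 0.91, and it was 0.595 without wild-type replicate 1, 0.363 without wild-type replicate 3 and 1.61 without deficient replicate 2.

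Of the other cell types in the tumours, the stroma, leukocyte and muscle lists did not pass at camera's preset correlation. Fibroblast, smooth muscle and stroma miRNAs had a mean difference of 0.15 over 16 members (adjusted p = 0.38), with 0.05 (SE 0.28) for miR-22-3p and 0.12 (SE 0.26) for miR-199a-3p. With 1 tumour left out miR-199a-3p ranged from 0.0227 (without wild-type replicate 3) to 0.29 (without deficient replicate 2), and with slide as a block miR-22-3p was 0.256. The list gave 0.234 without wild-type replicate 6 (camera adjusted p = 0.0205, and adjusted p = 0.632 with an estimated correlation) and 0.322 without deficient replicate 2 (camera adjusted p = 0.016, and adjusted p = 0.436 with an estimated correlation). Over all 13 tumours its adjusted p was 0.919 with an estimated correlation, and the mean difference was 0.0581 without wild-type replicate 3 and 0.0441 without deficient replicate 6. Leukocyte miRNAs gave −0.0615 over 7 members (adjusted p = 0.72), and 0.108 without scaling. miR-142-3p differed by 0.07 (SE 0.53), miR-142-5p by −0.11 (SE 0.57) and miR-342-3p by −0.06 (SE 0.20). Lists with fewer than 3 tested members had no list test. The endothelial miR-126-3p differed by 0.51 (SE 0.30) and miR-126-5p by 0.20 (SE 0.28), the latter from 0.0996 (without deficient replicate 1) to 0.422 (without deficient replicate 2). In the liver, kidney and gut list miR-192-5p differed by 0.09 (SE 0.21) and miR-194-5p by −0.20 (SE 0.31), and the hypoxia-induced miR-210-3p differed by −0.55 (SE 0.51). miR-210-3p was −0.137 with slide as a block, −0.209 without wild-type replicate 4, −0.342 without wild-type replicate 6 and −0.848 without wild-type replicate 5. Epithelial miR-200 miRNAs had 0 tested members of 12 on the array, and pancreatic miRNAs 0 of 6.

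Muscle miRNAs had 3 tested members and a mean difference of −0.262 (adjusted p = 0.646), with 0.02 (SE 1.05) for miR-133a-3p and −0.08 (SE 1.18) for miR-133b-3p. Their spread lay within the groups. miR-1a-3p, which the list missed because of its letter and which was chosen after its values were seen, was at 10.72 to 12.05 in 3 tumours (wild-type replicate 1, deficient replicates 3 and 4) and at 4.10 to 7.51 in the other 10. Without these 3 tumours 0 miRNAs passed. At camera's preset correlation 2 of the 5 lists kept their call, the Sfmbt2 and miR-17-92 lists. The miR-29, erythroid and neuronal lists had differences of −0.638, 1.09 and −0.368 (adjusted p of 0.0629, 0.055 and 0.0943), and the muscle list, from whose members the 3 tumours were chosen, had −1.07 (adjusted p = 0.00545). With an estimated correlation the adjusted p of these 6 lists without the 3 tumours was 0.538.

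**Figure D3:**
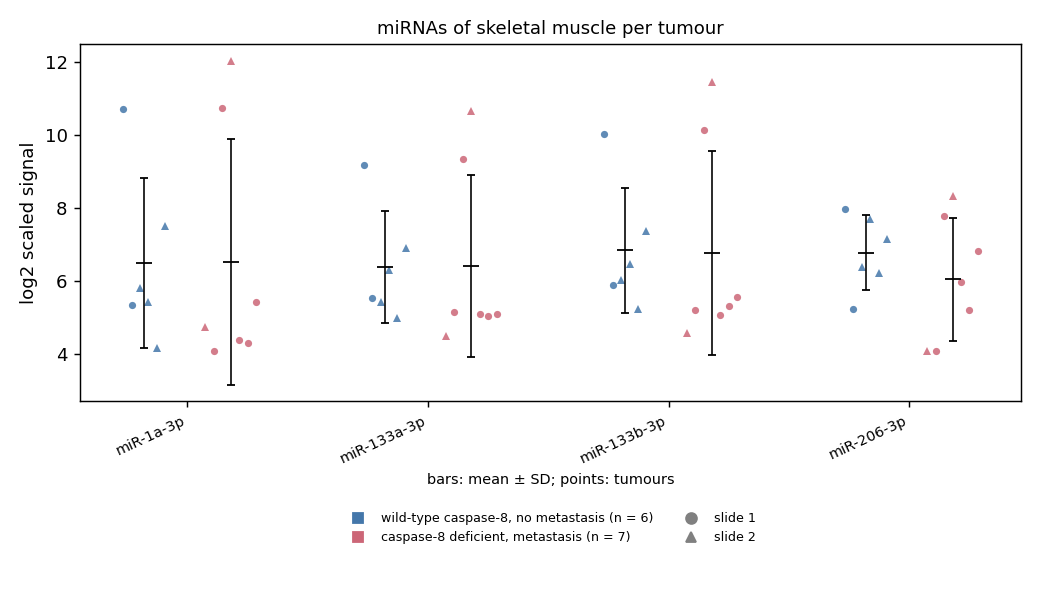
Levels of 4 skeletal muscle miRNAs (x axis) as log2 scaled signal (y axis), with 1 point per tumour, circles for slide 1, triangles for slide 2, and bars for mean ± SD of 6 wild-type and 7 deficient tumours. For miR-1a-3p 3 tumours lie between 10.72 and 12.05, 1 of them wild-type, and the other 10 between 4.10 and 7.51.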

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

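All tests of the 3 patterns weighed here were chosen after the results were seen. Dixon's ratio was computed in both groups for the 54 named miRNAs, 15 lists, the number of detected miRNAs and the summed signal. In 11 of these group values a tumour lay far from the rest of its group, where chance gives about 1 in 20. Deficient replicate 2 was lowest for miR-10b-5p (4.955, next 9.14), miR-199a-3p (8.885, next 9.75), miR-126-5p (4.36, next 5.51) and the retinoic acid and differentiation list (−0.307, next 0.0701). Deficient replicate 1 was highest for miR-451 (16.32, next 14.93), the erythroid list (1.84, next 0.402) and miR-194-5p (5.37, next 4.37). Deficient replicate 3 was lowest for miR-7a-5p (10.49, next 11.28). Among wild-type tumours, replicate 3 was highest for miR-598-3p (9.20, next 8.14), replicate 5 was highest for miR-34a-5p (10.24, next 8.53) and replicate 6 was lowest for miR-5109 (14.48, next 15.01). Of 57 miRNAs of mouse herpesviruses on the array, which the tests of the 419 mouse miRNAs left out, 13 were detected on at least 1 array and 6 on all 13 arrays. Their log2 levels ranged from 4.10 to 10.698.

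The 15 members named 5p of the Sfmbt2 list had a mean of 8.47 ± 0.91 (SD, n = 6) in wild-type and 7.33 ± 1.44 (SD, n = 7) in deficient tumours (difference −1.14, exact permutation p = 0.129), and the difference was −0.74 (exact permutation p = 0.234) without deficient replicate 2, the lowest at 4.928 and also the highest on principal component 1 at 21, and −1.44 (exact permutation p = 0.0455) without deficient replicate 4. Their mean followed the probe for the viral mghv-miR-M1-2-5p with Pearson r = 0.997 (permutation p = 1e-05, the smallest these permutations can give, adjusted p = 3e-05 over 3 relations) and Spearman rho = 0.989 (permutation p = 1e-05, adjusted p = 3e-05), with r = 0.995 without the 2 farthest tumours, 0.998 within slide 1 and 0.999 within slide 2, and 18 tested mouse miRNAs outside the list followed the same probe. This may reflect signal that is not specific to these miRNAs, since no label names an infection. A correlation cannot tell whether the viral probe, the mouse probes or both carry such signal. Transcription of the whole cluster stays open: the 5p and 3p members gave Pearson r = −0.46 (permutation p = 0.114, adjusted p = 0.114) and Spearman rho = −0.341 (permutation p = 0.254, adjusted p = 0.254), but r was −0.132 without the 2 farthest tumours, −0.527 within slide 1 and −0.228 within slide 2. With slide as a block the difference was −0.879 (exact permutation p = 0.295), which leaves a part of the slides and the genotype or metastasis of the tumours open.

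Muscle miRNAs were high in 3 tumours. These were noticed from miR-1a-3p, miR-133a-3p, miR-133b-3p and miR-206-3p together, so that their agreement is no test. RNA of skeletal muscle in the samples is a candidate explanation that stays open: of 8 detections among 11 other muscle miRNA forms 3, or 37.5%, fell in these tumours, where chance gives 23.1% (one-sided exact p = 0.287 over 286 choices of 3 tumours). miR-133a-5p was detected in 2 tumours, 2 of them among these 3, miR-208a-5p in 2 and 0, and miR-499-3p in 4 and 1. The 8 detections pool another arm of a high miRNA with other muscle miRNAs and are too few to decide. A difference between the slides was argued against, since slide accounted for 0.316% of the variance of the mean muscle level and tumours with high levels lay on both slides. Group accounted for 0.22%.

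Of the 10 miRNAs with the smallest p, the 7 with higher means had a joint mean of 6.91 ± 0.39 (SD, n = 6) in wild-type and 7.86 ± 0.46 (SD, n = 7) in deficient tumours, a contrast they were chosen for. The difference was 0.948 pooled and 0.862 with slide as a block, but a part of the slides stays open because the choice of these miRNAs favours a difference that is kept. Signal that is not specific to these miRNAs stays open: their mean and the probe for the viral mcmv-miR-M23-1-3p gave Pearson r = 0.738 (permutation p = 0.00365, adjusted p = 0.00548) and Spearman rho = 0.599 (permutation p = 0.0328, adjusted p = 0.0492), but r was 0.493 without the 2 farthest tumours, 0.494 within slide 1 and 0.865 within slide 2. That probe differed by 0.509 between the groups (exact permutation p = 0.231). The 2 viral probes used here were chosen after the values were seen, and 6 viral miRNAs were detected on all 13 arrays. The adjustment over 3 relations does not cover that choice. A link to genotype or metastasis was not tested apart from the group contrast itself.

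The grouping of the tumours was compared with other groupings, as 100 splits of the 13 tumours into 6 and 7, the real one included. For changed miRNAs this decides nothing, since the real count was 0 and all 100 splits give at least that. Of the splits 97 gave 0 miRNAs and 3 gave 1 or more, the highest 32. At an unadjusted p under 0.05, 44 splits gave at least the real 16 miRNAs, and the highest other gave 97. For the lists, 22 splits gave at least the real 5, and the highest other gave 7. Chance could not be excluded for these last counts. What sets the split with 32 miRNAs apart was not tested, and splitting by slide gave 0 changed miRNAs and 41 at an unadjusted p under 0.05.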

How the results depend on the processing

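Normexp, the omission of the 3 tumours with high muscle miRNAs and the omission of miRNAs that follow a viral probe were chosen after seeing the data. The count of changed miRNAs was 0 under all 32 alternatives, with smallest adjusted p from 0.0644 to 1 and 9 to 63 miRNAs at an unadjusted p under 0.05. The number of shifted lists was 5, and was 6 with array quality weights, where the miR-17-92 and miR-29 lists lost the call and the neuroendocrine, stroma and Dlk1-Dio3 lists gained it, 3 with quantile normalization, miRNAs detected on all 13 arrays, 4 times the floor, the series matrix values or without the 3 tumours with high muscle miRNAs, 1 with the replicate block, 0 with camera at an estimated correlation or with fry, and 4 or 5 in all other settings that keep the 13 tumours. Leaving out 1 tumour at a time gave 3 to 6 lists. Camera at an estimated correlation changed only the correlation between members, preset at 0.01. The estimates were 0.367 for the Sfmbt2, 0.551 for the miR-17-92, 0.899 for the miR-29, 0.882 for the erythroid and 0.141 for the neuronal list. The cause of the other changes in the number of lists was not tested, apart from the smaller number of miRNAs or tumours where the alternative itself removes them. The camera call at the preset correlation was counted over the settings other than leaving out 1 tumour. It was kept in 18 of 19 for the Sfmbt2 list, 17 of 19 for miR-17-92 and 15 of 19 for miR-29. For the erythroid list it was kept in 11 of 18 and for the neuronal list in 11 of 19. These counts leave out camera at an estimated correlation and fry, where 0 lists passed. The neuroendocrine list passed with slide as a block (−0.309) and array quality weights (−0.376), and the stroma list with array quality weights (0.367) and without wild-type replicate 6 (0.234) or deficient replicate 2 (0.322). With an estimated correlation in these settings the adjusted p was 0.468 and 0.558 for the neuroendocrine list, and 0.558, 0.632 and 0.436 for the stroma list. The muscle list passed without the 3 tumours with high muscle miRNAs (−1.07, and adjusted p = 0.538 with an estimated correlation), which were chosen from its members and miR-1a-3p, so that the choice itself favours this. Removing miRNAs that follow a viral probe takes out the members of the Sfmbt2 list that carry its difference, so that its loss is set by that choice. The replicate numbers did not pair the tumours: same-numbered tumours correlated at −0.22 to 0.194 in their deviations from the group means, 3 of 6 above 0.1, and 0 of 6 wild-type tumours correlated best with their own number. The difference in detected miRNAs was −7.4 to 15.4 when 1 tumour was left out. Leaving out the scaling moved the median difference of all tested miRNAs from 0.0413 to 0.218. Each slide was scanned in 1 pass, so that scan date was not run apart from slide. The following differences changed sign, the Sfmbt2 list having passed in the reported setting and the Dlk1-Dio3 list passing with array quality weights (adjusted p = 0.0181, and adjusted p = 0.752 with an estimated correlation), and the cause was not tested. With 4 times the floor, the differences were the muscle list 0.226, miR-133b-3p 0.407 and miR-7b-3p −0.0531. With the 75th percentile over all mouse miRNAs, the difference was let-7b-5p 0.0156. With the floor divided by 4, the differences were miR-194-5p 0.231 and miR-21-3p 0.348. With array quality weights, the differences were the Dlk1-Dio3 list −0.0556, the leukocyte list 0.185, the list of miR-290 and miR-302 0.0457, let-7b-5p 0.0307, miR-133a-3p −0.642, miR-142-5p 0.155, miR-154-3p −0.0744, miR-17-5p −0.00116, miR-192-5p −0.0242, miR-21-3p 0.153, miR-21-5p 0.128, miR-210-3p 0.225, miR-218-5p −0.176, miR-342-3p 0.03, miR-34a-5p 0.141 and miR-7b-3p −0.157. With the mean of log2 probe levels, the differences were miR-133b-3p 0.0649 and miR-7b-3p −0.0243. With no filter on detection, the difference was the let-7 list −0.00669. With no scaling between arrays, the differences were the leukocyte list 0.108, the list of miR-290 and miR-302 0.0933, let-7b-5p 0.164, let-7c-5p 0.135, miR-125b-5p 0.0712, miR-133b-3p 0.112, miR-142-5p 0.0882, miR-21-5p 0.0253, miR-342-3p 0.135, miR-34a-5p 0.0782, miR-375-3p 0.0517, miR-7a-1-3p 0.128 and miR-99a-5p 0.0967. With normexp, the differences were the Dlk1-Dio3 list −0.0116, the muscle list 0.0614, miR-126-5p −0.0278, miR-133b-3p 0.209, miR-192-5p −0.0964 and miR-7b-3p −0.0894. With quantile normalization, the differences were the let-7 list −0.0124, miR-133b-3p 0.0556, miR-142-3p −0.0068 and miR-7a-1-3p 0.0319. With the replicate block, the differences were miR-133b-3p 0.116 and miR-142-5p 0.031. With the series matrix values, the differences were miR-133b-3p 0.137, miR-194-5p 0.0653 and miR-21-3p 0.0173. With slide as a block, the differences were the let-7 list −0.000826, the leukocyte list 0.16, miR-142-5p 0.276, miR-194-5p 0.0315 and miR-7b-3p −0.145. With the total gene signal, the differences were the leukocyte list 0.00171, the list of miR-290 and miR-302 0.0423, miR-133a-3p −0.292, miR-142-5p 0.309 and miR-7a-1-3p 0.0692. Without miRNAs that follow a viral probe, the differences were the Sfmbt2 list 0.0832 and the list of miR-290 and miR-302 0.0757. Without the 3 tumours with high muscle miRNAs, the differences were the leukocyte list 0.0285, miR-133a-3p −0.85, miR-142-5p 0.119, miR-218-5p −0.00254, miR-375-3p 0.353, miR-7a-1-3p 0.0888 and miR-99a-5p 0.0615. Leaving out 1 tumour at a time gave differences over these ranges, which cross 0: the muscle list −0.886 to 0.217, the Dlk1-Dio3 list −0.0253 to 0.0956, the leukocyte list −0.281 to 0.219, the list of miR-290 and miR-302 −0.181 to 0.0806, the let-7 list −0.0517 to 0.0657, let-7c-5p −0.174 to 0.0431, let-7b-5p −0.151 to 0.0838, miR-34a-5p −0.302 to 0.219, miR-218-5p −0.0668 to 0.195, miR-375-3p −0.302 to 0.0483, miR-22-3p −0.147 to 0.169. The other such ranges were miR-342-3p −0.181 to 0.0584, miR-142-3p −0.207 to 0.463, miR-133b-3p −0.863 to 0.559, miR-133a-3p −0.685 to 0.585, miR-192-5p −0.00465 to 0.217, miR-194-5p −0.376 to 0.027, miR-154-3p −0.0333 to 0.215, miR-21-5p −0.352 to 0.0368, miR-99a-5p −0.259 to 0.0844, miR-142-5p −0.435 to 0.309, miR-7a-1-3p −0.233 to 0.0388, miR-7b-3p −0.121 to 0.176. With 4 times the floor, miR-7a-1-3p, miR-21-3p, miR-192-5p and miR-194-5p were at the floor on every array and had no value. Signal close to background limits such miRNAs.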

Other observations

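Detection of several lists is given over all 13 tumours. Of the 91 Dlk1-Dio3 miRNAs on the array 62 were detected in at least 1 tumour, as were 22 of 38 neuronal miRNAs and 18 of 29 in the list on retinoic acid and neuronal differentiation. Of the 22 miRNAs of the miR-290 and miR-302 clusters, which belong to embryonic stem cells, 7 were detected in at least 1 tumour. Of the 12 miR-200 family miRNAs 1 was detected, and of the 6 pancreatic miRNAs 0 were.

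The levels of 2 tumours stood apart from the rest on principal components of the 419 tested miRNAs. Component 1 held 35.9% of the variance, with deficient replicate 2 at 21, the highest of the 13 tumours, and component 2 held 22.2%, with wild-type replicate 4 at 17.9, also the highest. The correlation of 2 arrays of the same group ranged from 0.811 to 0.973, and no pair of arrays held identical values.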
